A study of Schizosaccharomyces pombe with 23 samples.

How the data were processed

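Chromatin from WT, cd39 and cd60 cells was precipitated with antibodies to Cnp1, GFP (for Mis6, Mis12 and Cnp3), H3me2K9 or Swi6. Per the labels, cells were grown at 33 °C and shifted to 18 °C for 2 h, fixed in 3% formaldehyde for 35 min, and sheared to fragments of 500 bp on average (300 to 1000 bp). IP DNA and input DNA were amplified, labelled with different dyes and hybridised together on 23 Agilent arrays of 45220 spots, of which 2513 are controls. The IP carried Cy5 except on 3 dye-swapped H3me2K9 arrays. The arrays fell on 9 slides and 9 scans. Of 20 array positions, 3 were used by 2 arrays each, the Mis6 pair of each strain, with different scans and labelling kits.

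Per the file headers, the intensity values were made by Agilent Feature Extraction 9.5.1.1, which removed spatial trends and multiplied each channel by 1 linear dye factor. The deposited value table holds the log2 ratio of IP over input, with dye-swapped arrays already turned. Its array medians lay between -0.14 and 0.02, its slope on the ratio computed here between 0.384 and 0.990, and 800 values were missing. Its direction and centring were read from the values, and the source of its differing scale is unknown. It was used as an alternative only.

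The log2 ratio of IP over input was computed from the processed intensities, without control spots and spots that the software marked as outliers (0 to 2670 per array). Each array's median was set to 0, with no loess or quantile step, so all values are relative to the array's median. Input values were the log2 input signal centred in the same way. Arrays of a dye-swapped pair were averaged to 1 replicate (r between them 0.97, 0.97 and 0.96, across probes). Gene values are means over at least 2 probes, and region values means over their probes. Saturated spots numbered 0 to 3 per array in the IP channel and 0 to 4 in the input channel.

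No source used here names the genome build of the array. Probe sequences were not used. The array's positions were laid on the reference assembly ASM294v3 in 64 windows, and the shift was sought at which the GC content under the probes varied least, since array probes are chosen within a narrow range of GC. In 55 windows this was no shift, and in the 9 windows right of cen1 on chromosome I a shift of 6149 to 6150 bp. The SD of GC between probes was 2.68% to 3.63% at the best shift, and its median over all shifts tried was 7.42% to 8.59%. The reference served for gene names only, and all printed positions are the array's. Names of the 692 measured genes right of that break rest on this match. In all 4821 of 5473 genes had 2 probes, and for 42675 probes the reference sequence at their place occurs once in the assembly. These match counts rest on the shift and are uncertain near its break, inside cen1. There the probes at I:3772932 and I:3773113 were given 10 and 9 matches, yet their input in cd39 was lower than in WT by -6.90 and -6.82.

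A domain was a run of at least 10 probes, with gaps of at most 2 kb, whose running median over 7 probes was at least 1. The 157 regions were the 50 merged Cnp1 domains, their 30 kb flanks, the 100 kb at chromosome ends, the surroundings of the mating-type region (10 kb to each side) and the rest of each chromosome. Regions overlap, and some flanks hold the same probes, so the 157 regions are 149 distinct sets of probes and counts of regions are not counts of separate places. Strains were compared within Mis6, within H3me2K9 and within the input with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment within each comparison. Probes and genes were called at an adjusted p under 0.05 and at least 2-fold, and regions at an adjusted p under 0.05. The cd60 H3me2K9 array, and any group left with 1 replicate, was assumed to vary like the others. Input values of 1 strain come from arrays of several targets. Both deletion strains were compared with the same WT arrays, so their calls against WT are not independent.

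Groups, comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, for each comparison of Mis6 or H3me2K9 with WT, up to 15 genes highest and 15 lowest by fold among called genes whose replicates did not overlap between strains, and members of the lists as examples. The lists were genes within 100 kb of each chromosome end, genes within 30 kb of the cen1 Cnp1 domain, the telomeric helicases, mating-type cassettes, heterochromatin islands, histones, highly transcribed genes, transfer RNA genes and Tf2 elements. Of 171 transfer RNA genes 0 had 2 probes. The regions and single probes given by name beyond these rules were chosen after their values were seen.

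Alternatives were normexp background correction (offset 50), no centring, loess, quantile normalization of the input, the deposited value table, dim or repeated probes left out, each replicate left out, replicate, kit, slide or scan as a block, and 50 kb ends. Added after the data were seen were arrays of doubt left out, the WT Mis6 pair averaged, array weights, the target as a block, genes right of cen1 on chromosome I left out, H3me2K9 of cd60 against cd39, and the gene comparison of Mis6 in cd60 against cd39. The tests were tested on simulated data in which 200 features (fewer for regions) were changed by a log2 difference of 2, 4 or 6. For Mis6 genes in cd39, 65.7%, 91.0% and 98.5% were called, and for Mis6 probes 0%, 28.4% and 42.4%. For H3me2K9 probes in cd60 0% were called at each size. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.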

Results

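Centromere and heterochromatin proteins were mapped on the chromosomes of the fission yeast Schizosaccharomyces pombe by chromatin immunoprecipitation and tiling arrays (ChIP-chip). Cnp1 is the histone H3 variant of centromeres, CENP-A. Mis6, Mis12 and Cnp3 are kinetochore proteins, here fused to GFP. H3me2K9 is histone H3 dimethylated at lysine 9, the mark of heterochromatin, and Swi6 is the HP1 protein that binds it. The strains were a wild type (WT), with its centromere of chromosome I (cen1) in place, and cd39 and cd60, which carry a functional centromere elsewhere on that chromosome. The 23 arrays gave 20 replicates after dye-swapped pairs were averaged. Mis6 had 2 replicates in each strain, and H3me2K9 had 2 in WT, 3 in cd39 and 1 in cd60. Cnp1 and Swi6 had 1 array per strain, and Mis12 and Cnp3 had 1 array in cd60 and none analysed here in the other strains. Each array carried 42707 genomic probes, a median of 265 bp apart, and 99.3% to 100% of the spots per array and channel lay well above background. Median signals ranged from 1281 to 2364 in the immunoprecipitated (IP) channel and from 925 to 2844 in the input channel. Across probes, which are not independent, r between replicates was 0.97 for Mis6 in WT, 0.37 in cd39 and 0.41 in cd60. For H3me2K9 it was 0.41 in WT and between -0.13 and 0.45 in cd39. The number of arrays limits the precision, and the p-values measure only the spread between these samples, which may be technical. Positions are those of the array design, whose genome build is not given in the sources used here.

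The input DNA showed which part of cen1 each strain lacked. All 10 probes between I:3752034 and I:3784777 had a lower mean input in both cd39 and cd60 than in WT. This interval holds the central part of cen1 and spans 32.7 kb in array positions. The shift of 6149 bp against the reference was placed inside it, between I:3769239 and I:3769439, so by that match it is longer in the reference. In cd39 the measured log2 differences, with spots not well above background at their measured value, lay between -8.66 and -6.69 with a median of -7.25, and in cd60 between -7.78 and -5.06 with a median of -6.41 (n = 6 input values in WT, 7 in cd39 and 7 in cd60). The neighbouring probes at I:3751577 and I:3785028 differed from WT by -0.81 and 1.12 in cd39 and by 0.36 and 2.49 in cd60, none of which passed the test. At the probe at I:3784546 input was at least 125-fold lower in cd39 than in WT (measured log2 means -10.25 ± 1.03 and -3.24 ± 0.96, SD; limma, adjusted p = 6.64e-05), a bound that is open to dye bias. That probe was well above background on 0 of 9 cd39 arrays and 7 of 7 WT arrays. The other deleted probes were well above background on 1 to 7 of the 9 cd39 arrays, and all 10 on 1 to 7 of the 7 cd60 arrays.

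Of all 42707 probes, limma called 11 lower and 0 higher in cd39, and 7 lower and 0 higher in cd60. Of these, 9 and 7 lay in the interval. The other 2 lay at II:31742 (-3.69) and II:3456874 (-3.59, adjusted p = 0.0327 each), and were named after their values were seen. Their input in cd39, -8.99 and -9.84, lay within the range of the deleted probes (-10.25 to -8.27), and they were well above background on 7 and 3 of the 9 cd39 arrays. Already in WT they were dim, at -5.30 and -6.25, against -3.24 to -0.86 for the deleted probes. In cd60 they stood at -5.70 and -7.79. Over the 10 probes the mean input of cd39 was below that of WT by -8.74 within slide 1, -7.49 within slide 3 and -7.52 within slides 7 and 8. In cd60 it was below by -9.54 within slide 1 and -5.74 within slide 5, and by -0.85 within slide 3, which held the Cnp1 array. On that array the deleted probes averaged -3.18, and on the other cd60 arrays -7.80 or less. With slide or scan as a block 6 or 4 probes were called in cd39 and 0 in cd60, and normexp background correction left 0 in both. Leaving out any of 5 replicates (the first H3me2K9 and Swi6 replicates of WT, the first Mis6 and H3me2K9 replicates of cd39, the second H3me2K9 replicate of WT) lowered the cd39 count to 7. In cd60 the count was 3 without the first H3me2K9, the Swi6, the second Mis6 or the second H3me2K9 replicate of WT, or without the Swi6 or either Mis6 replicate of cd60. It was 4 without the Cnp1 replicate of WT or the H3me2K9 or Cnp3 replicate of cd60.

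**Figure D1:**
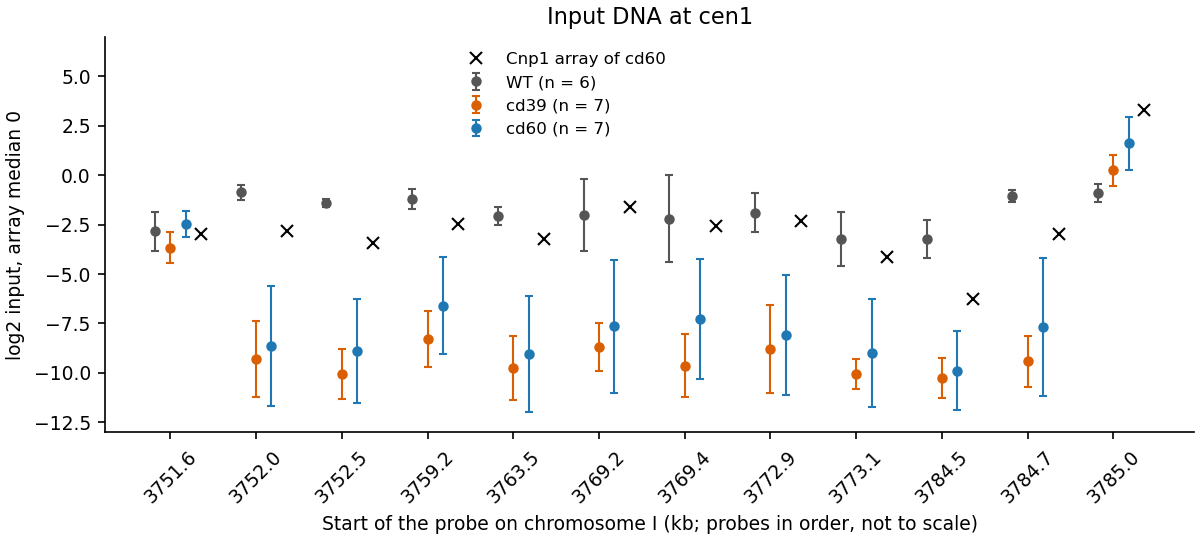
Input DNA at 12 probes at cen1, as log2 signal with each array's median at 0 (y axis), by probe start on chromosome I (x axis, in order, not to scale); points are means, bars SD, and crosses the Cnp1 array of cd60, which is also part of the cd60 mean. The 10 probes inside the deleted interval lie lower in cd39 and cd60 than in WT, while the crosses average -3.18 there.

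In cd39, Mis6 covered the left end of chromosome I, which was bare of it in WT. Over the Cnp1 domain of cd39 at I:57712-131698 the mean log2 IP over input of Mis6 was 2.65 ± 0.38 in cd39 and -0.14 ± 0.02 in WT (SD, n = 2 each), a difference of 2.79 (SE 0.23, adjusted p = 0.00573). Over the 100 kb at that end it was 2.83 in cd39 and -0.19 in WT. The gene ght3, of the hexose transporter family (I:83206-84613), had 90.6-fold higher Mis6 in cd39 (log2 difference 6.50, SE 0.29, adjusted p = 0.0292). It was the single gene of 4821 past the threshold, and 0 were lower (1 in all by limma). Of the 18 measured genes of the left end, 1 was higher, and 12 were higher with p adjusted over the list alone. Their median difference was 2.97. Beside ght3, the differences were 5.90 at shu1, a haem receptor, 3.53 at str3, a haem transporter, and 2.83 at dak2, a dihydroxyacetone kinase. At tlh1, the helicase gene at the tip, the difference was 0.20.

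The same comparison showed lower Mis6 beside cen1. On its left side, at I:3708542-3752572, Mis6 was 0.79 ± 0.05 in WT and -0.04 ± 0.01 in cd39 (SD, n = 2 each; difference -0.83, SE 0.07, adjusted p = 0.00573). Of 55 genes within 30 kb of the cen1 Cnp1 domain, 0 were called over all genes by limma, 25 had an unadjusted p under 0.05, and 6 were lower with p adjusted over the list alone. Their median difference was -0.71. Examples of the Mis6 levels in WT and cd39 were 1.25 and 0.14 at lys1, of lysine synthesis, and 2.42 and -0.50 at sdh1, a succinate dehydrogenase gene whose cd39 replicates stood at 0.68 and -1.67. Across 157 regions limma called 12 higher and 11 lower in cd39, and across single probes 0, with 5225 at an unadjusted p under 0.05. Within scan 2 the differences in Mis6 were 2.50 at the left-end domain, -0.80 on the left side of cen1 and 6.12 at ght3. The WT Mis6 arrays lay on slide 3 and those of cd39 and cd60 on slide 2. Strain and slide are therefore not separated in any Mis6 comparison with WT, also within scan 2. Both WT replicates of Mis6 agreed as closely as the arrays of a dye-swapped pair: with either left out, or both counted as 1 sample, 0 genes and 0 to 2 regions were called, and the adjusted p at the left-end domain was 0.0655, 0.0501 and 0.0522. Without the first cd39 replicate 0 genes and 12 regions were called, and without the second 2 genes. With the scan as a block 3 genes and 5 regions were called, and the left side of cen1 was no longer past the threshold (-0.82, adjusted p = 0.823). With the labelling kit as a block 0 genes and 14 regions were called. Without the second Mis6 arrays of cd39 and cd60, which vary most, the spread is that of the near-identical WT pair alone. The counts of that fit are given with the other alternatives below.

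In cd60, Mis6 covered the right end of chromosome I. Over the Cnp1 domain at I:5458345-5552712 the mean log2 IP over input of Mis6 was 3.27 ± 0.24 in cd60 and -0.01 ± 0.02 in WT (SD, n = 2 each), a difference of 3.27 (SE 0.13, adjusted p = 0.000435). The largest gene difference was 65.0-fold at SPAC869.03c (I:5506988-5508563; log2 6.02, SE 0.18, adjusted p = 0.00200). In all, 12 of 4821 genes had higher Mis6 and 0 lower, while 27 and 8 were called with the replicate number as a block, and 20 and 5 with normexp correction. They included SPAC869.04 (5.82), SPAC186.02c (5.45), pfl9, a cell surface flocculin gene (5.17), pcm2, a protein isoaspartate methyltransferase gene (3.55), gdt1 (3.48) and sul2, a sulfate transporter gene (3.44). Also called were SPAC186.07c (3.27), SPAC186.04c (3.08), SPAC186.08c (2.97) and gto1 (1.65). The remaining gene, SPAC27F1.10 at I:4319960-4320520 (1.73, adjusted p = 0.0489), lay outside the domain. Of the 24 measured genes of the right end, 10 were higher, and all 24 with p adjusted over the list alone, with a median difference of 3.46. At the left-end domain of cd39, Mis6 in cd60 was 0.16 ± 0.28 (difference from WT 0.30, adjusted p = 0.403).

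Beside cen1 the level of Mis6 was lower in cd60 as well. The left side of cen1 was at -0.06 ± 0.06 (SD, n = 2) against 0.79 in WT (difference -0.85, SE 0.07, adjusted p = 0.00551). Of the 55 genes near cen1, 0 were called by limma over all genes, 24 had an unadjusted p under 0.05, and 12 were lower with p adjusted over the list alone. Their median difference was -0.70. The flanks to the right of cen3 had more Mis6 in cd60 than in WT, for example by 0.70 at III:1153553-1183552 (adjusted p = 0.0235). Of 157 regions, limma called 21 higher and 7 lower in cd60. Of single Mis6 probes it called 0, with 8227 at an unadjusted p under 0.05. Within scan 2 the differences were 3.12 at the right-end domain and 5.87 at SPAC869.03c, between arrays of different slides. With either WT replicate left out, or both counted as 1 sample, 0 genes and 3, 5 and 3 regions were called, while the adjusted p at the right-end domain stayed at 0.0138 or less over 17 alternatives. Without the second cd60 replicate 6 genes and 7 regions were called, and without the first 51 regions. With the labelling kit or the scan as a block 2 or 7 genes and 6 or 5 regions were called, and with the scan the left side of cen1 was no longer past the threshold (-0.83, adjusted p = 0.641).

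Mis6 was also compared between both deletion strains directly. In cd60 it was lower than in cd39 at the left-end domain by -2.49 (SE 0.23, adjusted p = 0.00503) and higher at the right-end domain by 3.31 (SE 0.13, adjusted p = 0.000413). Both differences came from arrays of slide 2, which held all 4 replicates, and both passed the threshold in each of 18 alternatives. In a gene comparison added after the data were seen, 22 genes were higher and 8 lower in cd60 (limma, 4821 genes). Of these, 16 of the 22 lay in the list of the right end and 4 of the 8 in that of the left end. The Cnp1 domains reach beyond these lists of 100 kb. Of the other higher genes, mmf2 and gto1 lay inside the right-end domain of cd60. Of the other lower genes, toe4 lay inside the left-end domain of cd39 and SPAC11D3.14c across its edge. SPAC11D3.16c lay in a further Cnp1 domain of cd39 beside it. The remaining called genes lay outside these domains. The largest differences at these ends, named after their values were seen, were 6.09 at SPAC869.01 (adjusted p = 0.0354) and 6.07 at SPAC869.03c (0.00195) on the right, and -6.65 at ght3 (0.00599) and -6.51 at shu1 (0.0166) on the left. On the left side of cen1 the strains differed by -0.01 (adjusted p = 0.908). Of 157 regions, 23 were higher and 12 lower in cd60. Without either cd39 replicate, or without the second cd60 replicate, 22, 21 and 22 regions were called. With the kit or the scan as a block 13 and 6 were called. The count of 30 genes became 9, 9, 8 and 13 without the first or second cd39 or the first or second cd60 replicate, and 0 in limma with the kit as a block or the WT pair counted as 1 sample (381 and 338 at an unadjusted p under 0.05). Of single Mis6 probes limma called 0, with 6013 at an unadjusted p under 0.05.

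**Figure D2:**
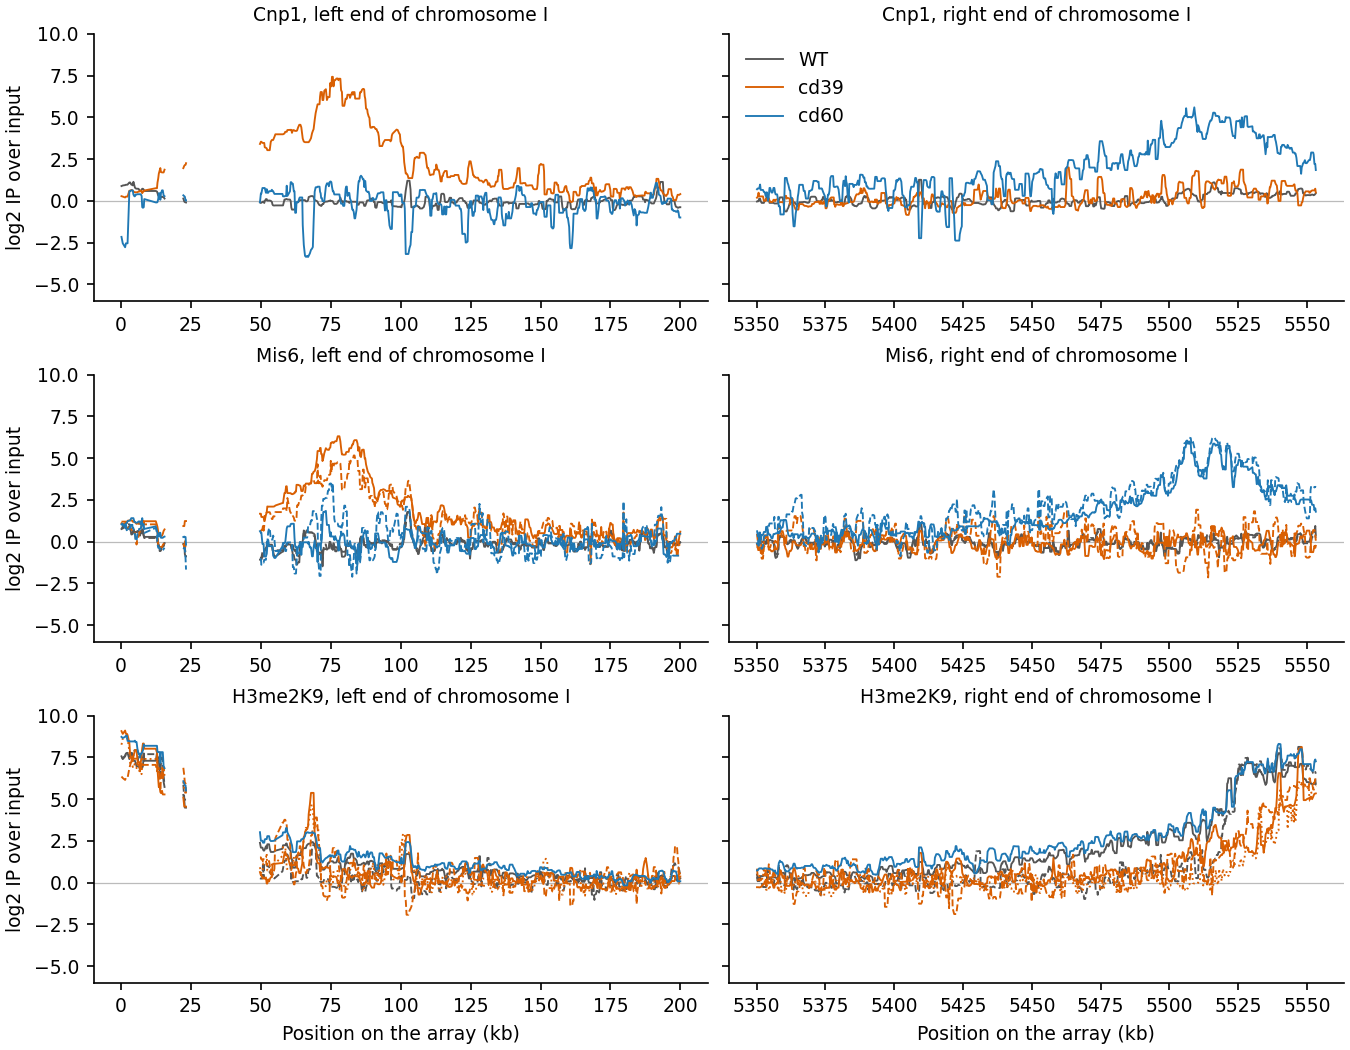
Log2 IP over input of Cnp1, Mis6 and H3me2K9 (y axis; running median over 7 probes) against array position in kb (x axis) at both ends of chromosome I; grey is WT, orange cd39 and blue cd60, and solid, dashed and dotted lines are replicates 1, 2 and 3. The highest running median of Cnp1 is 7.42 at the left end in cd39 and 5.60 at the right end in cd60.

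H3me2K9 was lower in cd39 than in WT at 3 genes of the right end of chromosome I and at per1 beside cen1. The right-end genes were pfl9 (5.65 ± 0.58 in WT and 1.59 ± 0.46 in cd39; difference -4.06, SE 0.41), SPAC186.06 (7.57 and 3.67; -3.90, SE 0.40) and SPAC186.04c (7.35 and 3.73; -3.62, SE 0.32). At per1, an amino acid permease gene, H3me2K9 was 3.26 ± 0.15 in WT and 0.18 ± 0.12 in cd39 (-3.08, SE 0.29). The adjusted p was 0.0355 for each, with SD over n = 2 replicates of WT and 3 of cd39. These were the 4 of 4821 genes called by limma, all lower. Of the 24 genes of the right end, 3 were lower, and 6 with p adjusted over the list alone, with a median difference of -1.55. Of the 55 genes near cen1, 1 was lower, and 10 with p adjusted over the list alone, with a median of -0.87. Examples near cen1 were emc5 with 2.79 in WT and -0.03 in cd39, and rad50 with 2.04 and 0.19. At tlh1, H3me2K9 was 7.66 ± 0.19 in WT and 7.65 ± 0.68 in cd39.

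By region, H3me2K9 over the 100 kb of the right end was 3.46 ± 0.85 in WT and 1.78 ± 0.42 in cd39 (adjusted p = 0.387), and on the left side of cen1 1.49 ± 0.47 and 0.20 ± 0.12 (adjusted p = 0.243). Over the left-end domain it was 0.71 in both strains. Limma called 0 of 157 regions and 0 of 42707 probes, with 9 regions and 546 probes at an unadjusted p under 0.05. Within slide 1 and within slides 7 and 8 the differences were -4.11 and -4.17 at pfl9, -3.59 and -3.80 at SPAC186.04c, -4.11 and -4.34 at SPAC186.06, -3.11 and -2.90 at per1, and -1.94 and -1.56 over the right end. The count of called genes was 12 with the slide as a block, of which 2 were higher, and 0 with the kit as a block. It was 0 without either WT replicate or without the first or the third cd39 replicate, and 7 without the second. Without the second WT replicate 10 regions were called. Loess, normexp correction and the deposited value table each left 0 genes.

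In cd60, with 1 H3me2K9 array assumed to vary like the other groups, H3me2K9 at the right end stood at 4.39 against 3.46 ± 0.85 in WT (difference 0.93, SE 0.59, adjusted p = 0.287). At pfl9, SPAC186.06 and SPAC186.04c the array gave 5.64, 7.59 and 7.29. On the left side of cen1 it gave -0.00 against 1.49 in WT (adjusted p = 0.141), and at per1 -0.01. Limma called 0 of 4821 genes, 0 of 42707 probes and 0 of 157 regions against WT, with 91 probes and 48 regions at an unadjusted p under 0.05. Near cen1, 1 of 55 genes was lower with p adjusted over the list alone, and the median difference was -0.98. Within slide 1 the differences from WT were -3.38 at per1 and 0.33 over the right end. Without the first WT replicate, or with the kit as a block, 51 regions were called, 49 higher and 2 lower.

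The targets with 1 array per strain had no test. Cnp1 formed a domain of 74.0 kb at I:57712-131698 in cd39 and of 94.4 kb at I:5458345-5552712 in cd60. These edges follow the limit of 2 kb on gaps between probes, and further Cnp1 domains lay beside them at I:49335-55243 (mean 3.59), I:134096-136383 and I:140584-144595 in cd39 and at I:5436130-5454902 (mean 1.64) in cd60. In WT the longest Cnp1 domain ran over I:3708542-3752572, on the left side of cen1, with a mean of 1.59. The core of cen1 could not be called as a domain, since its few probes lie too far apart. WT Cnp1 was higher there, at 8.40, 8.81, 7.29 and 8.16 for the probes at I:3769239, I:3769439, I:3772932 and I:3773113. Mis6 domains in cd39 ran over I:57712-123573 in the first replicate and I:57712-104875 in the second. In cd60 they began at I:5458636 and I:5439489 and reached I:5552712. In cd60 Mis12 covered I:5490352-5552712 (62.4 kb) and Cnp3 I:5473938-5552712 (78.8 kb). Swi6 covered the last 29.1 kb of measured probes at the right end in WT, 28.5 kb in cd60 and 16.1 kb in cd39. At a threshold of 1.5 the longest Swi6 domain there ran over I:5523821-5552712 in WT, I:5540748-5552712 in cd39 and I:5540952-5545847 (4.90 kb) in cd60, where it was the shortest. In cd39 a further Swi6 domain of 12.4 kb lay at I:69237-81681, inside the Cnp1 domain. The Cnp3 array of cd60 (I:70273-81023) and its second Mis6 replicate (I:67923-80791) had domains at nearly the same place, where Cnp1 had none in cd60. With normexp correction that of Mis6 was I:67923-77534, while the longest Cnp3 domain of the left end was 3.93 kb at I:86173-90102. Across probes, the Swi6 array had r = 0.80 with the Cnp1 array in cd39, 0.93 in cd60 and 0.68 in WT. The inputs of these pairs had r = 0.99, 0.97 and 0.99, so a similar input may be a source, which was not tested. Cnp1 in cd39 was also above the threshold over 10.2 kb at I:5513250-5523450. Cnp1 and first-replicate Mis6 domains shared 0.424 of their joint length in cd39, 0.462 in cd60 and 0.280 in WT. With the second Mis6 replicates the shares were 0.139, 0.168 and 0.283, so the order of the strains depended on the replicate. The Cnp3 array called 296 domains, and the second Mis6 replicates of cd60 and cd39 called 171 and 119, against 3 to 43 for the other replicates. With normexp correction the Cnp3 array called 45, within the 7 to 56 of the others, and the second Mis6 replicates 163 and 109.

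**Figure D3:**
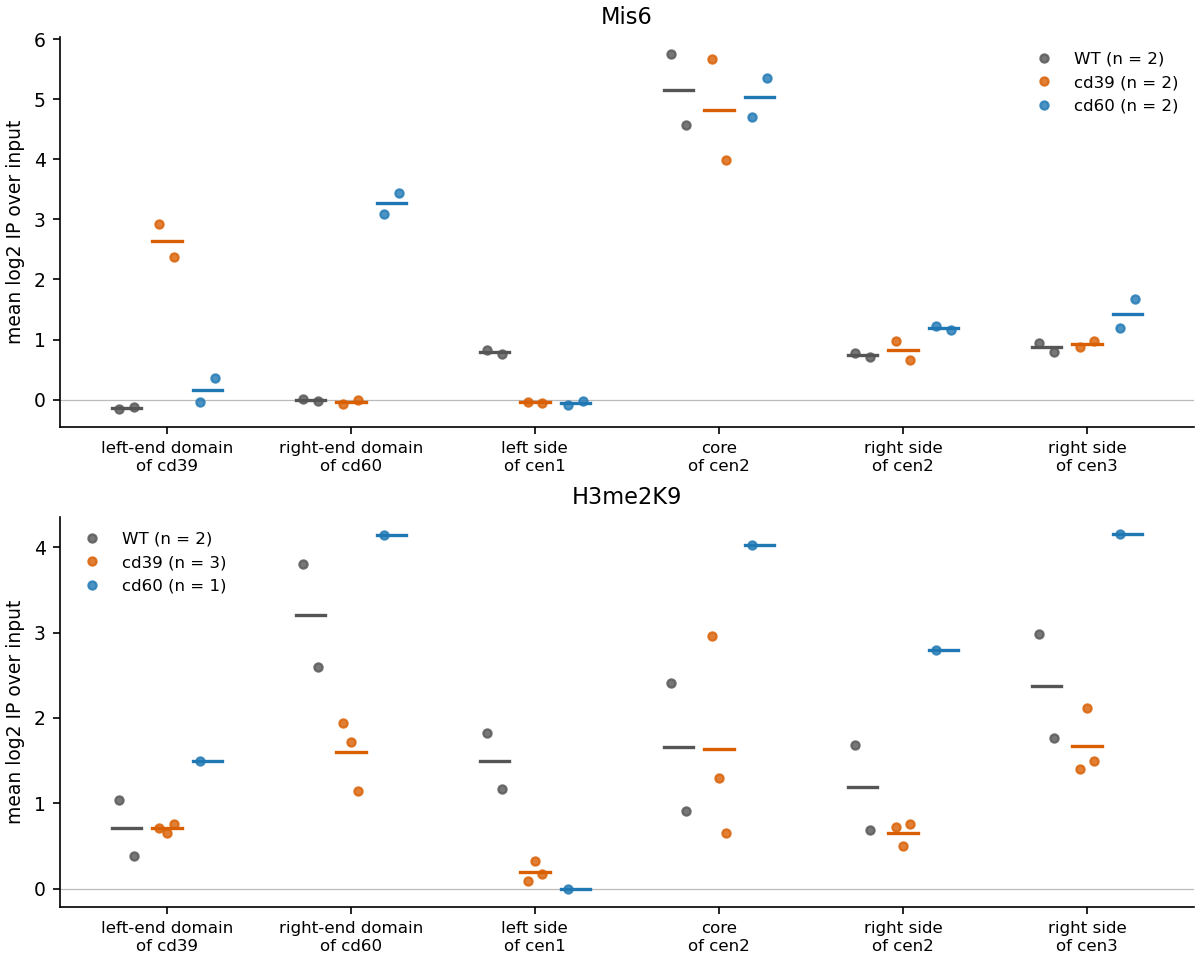
Mean log2 IP over input (y axis) of Mis6 and H3me2K9 in 6 regions (x axis); each point is a replicate and each bar the strain's mean. Mis6 of cd39 and cd60 stands apart at the left-end and the right-end domain, and at the core of cen2 it lies between 3.99 and 5.74 in all 6 replicates.

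At the centromeres left in place, Mis6 over the core of cen2 (II:1620842-1627570) was 5.15 ± 0.84 in WT, 4.83 ± 1.18 in cd39 and 5.03 ± 0.47 in cd60 (SD, n = 2 each), and neither difference from WT passed the test (adjusted p = 0.870 and 0.908). Cnp1 there was 7.36, 6.22 and 4.48. At the ends of chromosomes II and III, with 21, 27, 38 and 36 measured genes, limma called 0 genes for either target and strain, also with p adjusted over the list alone, and up to 11 had an unadjusted p under 0.05. Of 8 measured histone genes 0 were called, with 0 or 1 at an unadjusted p under 0.05. Of the 4 genes of heterochromatin islands limma called 0 in each comparison, with 0 at an unadjusted p under 0.05. H3me2K9 was 5.94 ± 0.49 in WT, 5.57 ± 0.82 in cd39 and 6.26 in cd60 at mei4, and 5.07, 4.79 and 5.21 at ssm4. The 10 highly transcribed genes had a median Mis6 of 2.17 in WT, 1.46 in cd39 and 1.23 in cd60. Limma called 0 of them over all genes, with 3 in cd39 and 4 in cd60 at an unadjusted p under 0.05, and 3 and 2 lower with p adjusted over the list alone. The level of adh1, alcohol dehydrogenase, was 2.42 in WT, 1.19 in cd39 and 1.19 in cd60. Genes of the mating-type cassettes, transfer RNA genes and Tf2 elements had 0 members with 2 probes.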

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

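All tests of explanations given here were chosen after the result was seen, except the comparison of strains for Mis6, which was planned. The H3me2K9 comparison of cd60 with cd39 and its alternatives were added later.

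The cd60 and cd39 strains differed in Mis6 at both ends of chromosome I. In cd60 minus cd39, the left-end domain differed by -2.49 (adjusted p = 0.00503), the 100 kb of the left end by -2.62 (adjusted p = 0.00556), the right-end domain by 3.31 and the 100 kb of the right end by 3.47 (adjusted p = 0.000413 each). On the single H3me2K9 array of cd60 the level stood above the mean of cd39 by 2.53 at the right-end domain, 2.61 over the right end of chromosome I, 2.14 on the right side of cen2 and 2.47 on the right side of cen3 (adjusted p = 0.0318 each). The test assumes that this array varies like the other groups, and with 1 array the strain is not separated from the array. The array went closely with the first WT replicate, also of slide 1 (r = 0.91 across probes), which had H3me2K9 domains at II:1647231-1699015 and III:1140819-1211361, so signal there was not particular to cd60. In all 42 of 157 regions were called, all higher in cd60. They overlap, and make 39 distinct sets of probes in 8 separate stretches. The count was 0 without any of the 3 cd39 replicates (adjusted p = 0.0770 to 0.0996 for the regions named here). Within slide 1, which held arrays of both strains, the H3me2K9 differences were 2.27 over the right end, 2.08 on the right side of cen2 and 2.75 on the right side of cen3.

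In the input, 5 of 36 groups held a sample far from the others. Chance gives about 1 in 20 groups, but the groups of a strain share the same arrays, so this rate is no yardstick for the count. The second H3me2K9 replicate of WT stood at -1.09 in the second domain right of cen1. The second H3me2K9 replicate of cd39 stood at -0.41 in the left-end domain and at 0.090 on the right side of cen3. These H3me2K9 replicates of WT and cd39 are averages of dye-swapped arrays, with input in both dyes. The second Mis6 replicate of cd39 stood at 0.76 on the right side of cen1.

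The Cnp1 array of cd60 stood at -3.18 in the deleted interval, where the next cd60 input was at -7.80. A wrong strain label is argued against by the right-end domain, which had a mean of 3.21 in log2 IP over input on this array. Chromatin of a strain with cen1, mixed in before the precipitation, is argued against as the whole source by the 7 deleted probes with 1 genome match. These lay -4.34 from the WT Cnp1 array, at a mean IP over input of -0.65. The deleted probes differed, however. Those at I:3769239, I:3769439, I:3772932 and I:3773113 stood at 1.23, 1.09, 0.50 and 1.65, where WT Cnp1 was 7.29 to 8.81. The outer probes at I:3752034 and I:3784718 stood at -1.56 and -1.91, where WT was 3.15 and 1.69. The mean therefore cannot tell whether the cen1 DNA in the sample or on the slide carried some Cnp1. No biological explanation was tested.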

How the results depend on the processing

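The alternatives with doubted arrays left out, the WT Mis6 pair averaged, array weights, the target as a block, or without genes right of cen1 on chromosome I, and those for H3me2K9 and for Mis6 genes between cd60 and cd39, were chosen after the data were seen. No alternative reversed the sign of a region or gene difference checked here. The order of the strains by Swi6 domain length at the right end did change with the threshold, as given below. Mis6 at the right-end domain of cd60 kept its direction and its side of the threshold in all 17 alternatives (3.06 to 3.61 against WT), and both ends did so between cd60 and cd39 in all 18 (-2.96 to -2.22 and 3.14 to 3.51). The labels do not say what a replicate number shares between strains. Deviations of same-numbered Mis6 replicates from their strain's mean went together in cd39 and cd60 (r = 0.94 in IP over input, 0.87 and 0.88 in the input, across probes) and hardly in WT and cd39 (0.05) or WT and cd60 (0.02). The effect of the replicate block on the counts is given below. The cause was not tested for any change below, except that fewer samples or genes enter where some are left out. Not estimable were the slide as a block for Mis6 against WT, the scan as a block for H3me2K9, and the replicate block for H3me2K9 in cd60. For Mis6 between cd60 and cd39, only cd39 and cd60 replicates were left out in turn. A fit without a WT replicate would take its spread from cd39 and cd60 alone, as that with the WT pair averaged does. Without the doubted Mis6 arrays the spread is that of the near-identical WT pair alone, for probes, genes and regions.

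For Mis6 probes 0 were called in each comparison. With the doubted second Mis6 arrays left out 6833 were called in cd39, 10344 in cd60 and 8729 between them, where the spread is that of the near-identical WT pair alone. Array weights gave 2 in cd39, and the scan as a block 54 between the strains. With 1 replicate left out the count was 0 in each.

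For Mis6 genes in cd39 the count of 1 became 2 with normexp, 0 without centring, 5 with loess, 2 with the deposited value table, 0 with the kit as a block, 3 with the scan as a block, 137 without the doubted arrays (55 higher, 82 lower), 0 with the WT pair averaged and 15 with array weights (13 and 2). Leaving out 1 replicate gave 0 to 2. In cd60 the count of 12, all higher, became 25 with normexp (20 higher, 5 lower), 22 without centring (19 and 3), 35 with the replicate block (27 and 8), 2 with the kit, 7 with the scan, 234 without the doubted arrays (115 and 119), 0 with the WT pair averaged, 25 with array weights (23 and 2) and 0 without genes right of cen1 on chromosome I. With 1 replicate left out the count was 0 to 9. Between cd60 and cd39 the count of 30 became 0 with the kit, 182 without the doubted arrays, 0 with the WT pair averaged, 16 with array weights, 4 without genes right of cen1 on chromosome I and 31 with the replicate block. With 1 replicate left out it was 8 to 13.

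For Mis6 regions in cd39 the count of 23 became 9 with normexp, 5 without centring, 14 with the kit, 5 with the scan, 90 without the doubted arrays and 0 with the WT pair averaged. Leaving out 1 replicate gave 0 to 16. In cd60 the count of 28 became 50 with the replicate block, 6 with the kit, 5 with the scan, 104 without the doubted arrays, 3 with the WT pair averaged and 48 with array weights. With 1 replicate left out the count was 3 to 51. Between the strains the count of 35 became 13 with the kit, 6 with the scan, 93 without the doubted arrays, 9 with the WT pair averaged and 43 with the replicate block. Leaving out 1 replicate gave 21 to 45.

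The left-end domain of cd39 was at 2.79 with the WT pair averaged (adjusted p = 0.0522; 2.13e-07 to 0.0655 over its alternatives), and at 2.52 to 3.06 with 1 replicate left out. The left side of cen1 in cd39 was at -0.96 without centring, -0.82 with the scan as a block and -0.83 with the WT pair averaged (adjusted p = 6.70e-05 to 0.823 over its alternatives), and at -0.87 to -0.80 with 1 replicate left out. In cd60 it was at -0.83 with the scan and -0.85 with the WT pair averaged (adjusted p = 4.88e-05 to 0.641 over its alternatives), and at -0.89 to -0.81 with 1 replicate left out.

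For H3me2K9 in cd39, array weights gave 10 probes against 0. The count of 4 genes became 0 with normexp, 0 with loess, 0 with the deposited value table, 2 without the dye-swapped arrays, 8 with the replicate block, 0 with the kit, 12 with the slide (2 higher, 10 lower), 10 with array weights and 0 without genes right of cen1 on chromosome I. With 1 replicate left out the count was 0 to 7. The count of 0 regions became 4 with the slide and 2 with 50 kb ends, and 0 to 10 with 1 replicate left out. In cd60 array weights gave 1 gene against 0, and the kit as a block 51 regions against 0. Leaving out 1 replicate gave 0 to 51 regions.

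For H3me2K9 between cd60 and cd39 the count of 42 regions became 0 without any of the 3 cd39 replicates and 63 without either WT replicate, and it was 50 with the slide as a block. With 1 replicate left out the right-end domain of cd60 was at 2.31 to 2.70, the right end of chromosome I at 2.38 to 2.79, the right side of cen2 at 2.06 to 2.19 and the right side of cen3 at 2.34 to 2.70. Over these alternatives the adjusted p was 0.00774 to 0.0996 for the right-end domain, the right end and the right side of cen3, and 0.00835 to 0.0996 for the right side of cen2.

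For input probes in cd39 the count of 11 became 0 with normexp, 6 with quantile normalization, 6 with the slide, 4 with the scan and 6107 with array weights (468 higher, 5639 lower). With 1 replicate left out the count was 7 to 11. In cd60 the count of 7 became 0 with normexp, 4 with quantile normalization, 3 with the replicate block, 0 with the slide, 0 with the scan, 2 without the doubted arrays, 2 with the target as a block and 49 with array weights. Leaving out 1 replicate gave 3 to 9. The count of 2 input regions became 0 with normexp and 62 with array weights in cd39 (4 higher, 58 lower), and 0 with normexp and 0 with the scan in cd60. It stayed at 2 with 1 replicate left out.

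The Cnp1 domain of the left end was 44.7 kb long at a threshold of 1.5 and 98.8 kb at the lower threshold of a 1.5-fold enrichment. That of the right end was 117 kb at that lower threshold and 117 kb with a window of 3 probes. The longest Swi6 domain of the right end was 28.9 kb in WT and 4.90 kb in cd60 at a threshold of 1.5, shorter in cd60 than in cd39, and 31.8 kb in WT, 22.4 kb in cd39 and 37.9 kb in cd60 at the lower threshold. The Cnp3 array called 45 domains with normexp (275 kb in all) against 296 (1557 kb). Signal over background limits the input at the deleted probes and also at the called probes II:31742 and II:3456874, which were not well above background on all cd39 arrays. Leaving out probes whose input was not well above background on every WT array kept 42494 of 42707 probes and left the counts of 11 and 7 as they were.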

Other observations

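All tests of explanations in this part were chosen after the result was seen, and the limits of those on strong IP signal and on unspecific precipitation were revised after their values were seen. The exception is the test of base composition, whose limits were set before its result was seen.

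Around the mating-type region, at mat3, H3me2K9 was 0.59 ± 0.44 in WT, 0.63 ± 0.11 in cd39 and 1.02 on the cd60 array. On the right side of cen2 Mis6 was 0.74 in WT, 0.82 in cd39 and 1.19 in cd60. At the tip of chromosome I, Swi6 formed a domain over I:1742-8359 in WT and in cd39, and over I:2975-8359 in cd60. With only probes of a single genome match, no Swi6 domain was left at the left end in WT or cd60. In cd39 the Swi6 domains of the genome then numbered 15 (83.55 kb in all) against 17 (93.64 kb). In WT and cd60 this domain thus rests on probes whose sequence also occurs elsewhere, and its place is uncertain. In cd39 a further Swi6 domain covered the core of cen2 at II:1620842-1627570.

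Some arrays of different targets or strains went together across probes, which are not independent, more closely than replicates of cd39 or cd60. Cnp1 and Swi6 had r = 0.93 in cd60, 0.80 in cd39 and 0.68 in WT, and their inputs 0.97, 0.99 and 0.99. The ratios alone thus do not show that both proteins lie at the same places. The first H3me2K9 replicate of WT had r = 0.91 with the H3me2K9 array of cd60, and the second Mis6 replicates of cd39 and cd60 had 0.82. Cnp3 in cd60 had 0.66 with Cnp1 and 0.64 with Swi6. Other arrays opposed each other. The first H3me2K9 replicate of cd39 had r = -0.52 with Swi6 in cd60, -0.41 with Cnp1 in cd60 and -0.33 with Cnp3 in cd60. Swi6 in WT had r = -0.31 with Cnp1 and -0.31 with Cnp3 in cd60.

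The gene tlh1 gave a lower mean input signal on H3me2K9 arrays with input in Cy3 than on those of other targets, by -3.66 (SE 0.54). The other targets include Swi6, whose WT array stood at -1.41, within the range of these H3me2K9 arrays (-3.75 to -1.05). The number of DNA copies stays open: arrays of a dye-swapped pair hold the same DNA and differed in input at tlh1 by up to 3.67, but a dye bias there would part them with any number of copies, and no other target had input in Cy5. A strong IP signal in the same spot could lower the input signal. On the Swi6 arrays of WT, cd39 and cd60, input at tlh1 was -1.41, 0.11 and 0.88, and IP over input 4.32, 3.08 and 2.16. This order is the one that explanation predicts, but each value is 1 array, and a lower input by itself raises IP over input. Over the 50 kb at the right end of chromosome I the input was lower on the H3me2K9 arrays by -0.57 (SE 0.30), which is within the spread of the limit set, so this stays open too. No biological explanation was tested.

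The 10 highly transcribed genes had a median IP over input above 0 on 16 of 20 replicates. Base composition as the whole source is argued against by 15 of 20 replicates on which the list's median lay above the central range of 10000 random lists of matched GC. Unspecific precipitation of transcribed genes may be a source, and it stays open. The median lay below 0 on the Cnp1, Swi6 and Cnp3 arrays of cd60 (-2.52, -2.04 and -1.30) and on the second H3me2K9 replicate of cd39 (-1.93). Random lists of matched GC also had medians below 0 there (-1.92, -1.78, -1.41 and -1.01). On these 3 arrays of cd60 the list lay at percentiles 8.39, 26.4 and 61.0 of the random lists, so base composition is not argued against for them, and on the H3me2K9 replicate it lay at percentile 0.010. No biological explanation was tested.

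Other splits of the input values were drawn, 100 for each count. For the 11 probes of cd39, 1 split had as many calls, the real one (highest other 0), which argues against chance as the whole source. For the 7 probes of cd60, 2 splits had as many, the real one included (highest other 3400). For the 2 regions of cd39 it was 3 splits (highest other 4), and for the 2 regions of cd60 4 splits (highest other 28). Since other splits gave more calls, these counts alone do not exclude chance. The splits do not keep slide or scan together. A split that mixes the strains also mixes samples with and without the deletion, so few calls in the interval follow from the deletion. The calls at II:31742 and II:3456874 cannot be judged apart from the interval in this way. The place and size of the calls in the interval do argue against chance there. All 7 probes lie among the 10 of the deleted interval, and the 2 regions hold the same 6 probes of it. The mean input of the 10 probes was -7.85 or less on all 7 cd39 replicates and -7.80 or less on 6 of 7 in cd60 (-3.18 on the Cnp1 array), against -2.71 to -1.15 in WT. The split with 3400 probes and 28 regions points to a structure of the samples: all 6 arrays on its smaller side lay on slides 2, 3 and 4, and the larger side held 1 array from slide 2 and none from slides 3 and 4. With the slide as a block 0 probes and 2 regions were called in cd60, and with the scan as a block 0 and 0. In cd39 2 regions were called with either.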
